A study of Drosophila melanogaster with 2 samples.

How the data were processed

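The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from whole Drosophila melanogaster pupae aged 24 hours, males and females pooled, of a transgenic line that carries CG13204 with green fluorescent protein fused to its C terminus. The samples form 1 group of 2 biological replicates, numbered 2 and 3 in the labels, so no comparison between conditions was possible. Per the labels, chromatin was broken by sonication. The labels disagree on one point: title, assay and antibody fields describe both samples as immunoprecipitations of a transcription factor, while a free-text line of both speaks of an input control. The peak lists are those of an immunoprecipitation set against a control, per the notes deposited with the files, and were used as such.

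The 4 peak lists are on build dm6, per the file headers and notes. Each replicate had a relaxed list of 30000 peaks made from its own alignments and 1 control alignment, a further relaxed list of 30000 peaks came from both replicates pooled, and a set of 5796 reproducible peaks was derived from these by the irreproducible discovery rate, per the deposited notes. The peak caller, the aligner and their versions are not given in the sources used here. The deposited signal value of each peak is the caller's own score of the peak against the control; it has no stated unit, is not scaled between lists, and was used to describe and rank peaks and to compare the median-centred replicates. The deposited −log10 q column reached its maximum in 98.8% of the reproducible peaks and was used to rank nothing. The deposited summit offset, another column, gives the peak's position to the base. The 5796 reproducible peaks were the 5796 strongest of the pooled list, so that set is a single threshold on the pooled signal. All peaks lay on chromosome arms X, 2L, 2R, 3L, 3R and 4. No read counts were used here, so the sequencing depth of each replicate is unknown and no interval that needs it is given.

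Genes, start sites, exons and untranslated regions were taken from Ensembl release 115 (annotation BDGP6 version 54, the coordinates of dm6), without transposable elements, and sequence from the RefSeq assembly of the same build. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A summit within 500 bp of any annotated start site was called a promoter summit and any other a distal summit, and a gene with such a summit was called bound. Distal summits were assigned, in order of precedence, to 5′ untranslated region, coding exon, 3′ untranslated region, non-coding exon, intron or intergenic sequence. Replicate summits within 100 bp were matched. Random positions came from 1000 placements along the same arms. Gene lists (27) and motifs (24) were fixed before the data were examined, and so were the tests, the thresholds and several alternatives. Each list was tested with Fisher's exact test, two-sided, against the other protein-coding genes on the arms, with Benjamini-Hochberg adjustment over the lists. In the lists 17 symbols were updated from RefSeq synonyms, and 11 names had no match of their own, some of them second names of genes already in the list. Motifs and 6-mers were searched on both strands in 200-bp windows on the summits and in windows 1000 bp to each side that held no reproducible summit. Differences in median signal were tested with 100000 permutations. Peaks and genes are not independent replicates, so these p-values describe the spread over peaks or genes within 1 group.

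Named genes followed a rule fixed before the data were examined: the protein-coding gene with the nearest start site to each of the 20 strongest peaks, up to 4 bound members with the highest signal of each list past the threshold of 0.05, up to 2 of each other list, CG13204, and the 5 strongest distal peaks. Other genes named were chosen after their values were seen, and the text says so.

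The code was tested on simulated data. Planted replicate shares (81.6% planted, 81.0% found over 5796 peaks) and a planted list of 27 genes (called in 100% of 20 runs) were recovered. No motif or 6-mer was called at random positions. No list was called when genes drawn at random were bound at their first start site. That check cannot show an effect of gene length or number of start sites on the list test. Fisher's test of X against autosomes called 13.5% of 200 random gene sets at a threshold of 5%, and the cause was not tested; draws of random start sites, added for this reason, put 4% of 200 sets outside the central 95% of other draws. Alternatives fixed before the data were examined were other summit distances and promoter windows, interval overlap, the stronger peaks alone, all annotated genes as background, rotation of the gene order, shuffled sequence, distal peaks alone, and each replicate left out, which meant the 5796 strongest peaks of the other replicate. Alternatives chosen after seeing the data were rotation of all peaks, draws of genes alike in start sites and length, peaks found in both replicate lists, windows matched on GC content, summits at least 200 bp apart, and the draws of random start sites. Signal tracks were not analysed here.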

Results

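Peak lists from ChIP-seq of GFP-tagged CG13204 in whole pupae were analysed for 2 biological replicates, numbered 2 and 3, of 1 group. The depth of the libraries is unknown. The reproducible set held 5796 peaks in 5316 separate regions with a median width of 430 bp, which covered 1991843 bp. Signal values are the caller's own, as deposited.

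The strongest peak of the reproducible set lay at CG13204 itself, the gene that carries the tag. CG13204 (FBgn0033627) is annotated on the plus strand of 2R from 11366710 to 11370287 (dm6), with start sites at 11366710 and 11368286. A region of 3702 bp, from 11364025 to 11367726, was the widest of the set and held 5 summits. The strongest, at 11366579, lay 131 bp upstream of a start site and had a signal of 9785, with 4740.4 in replicate 2 and 5086 in replicate 3, rank 1 in both. A summit at 11367431 in an intron of CG13204 had a signal of 5660.35, and intergenic summits 1927 bp, 1605 bp and 1394 bp upstream of a start site had 5267, 3097 and 595. Of the 20 strongest peaks of the set, 4 lay in this region. The signal has no error beyond the 2 replicate values.

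**Figure D1:**
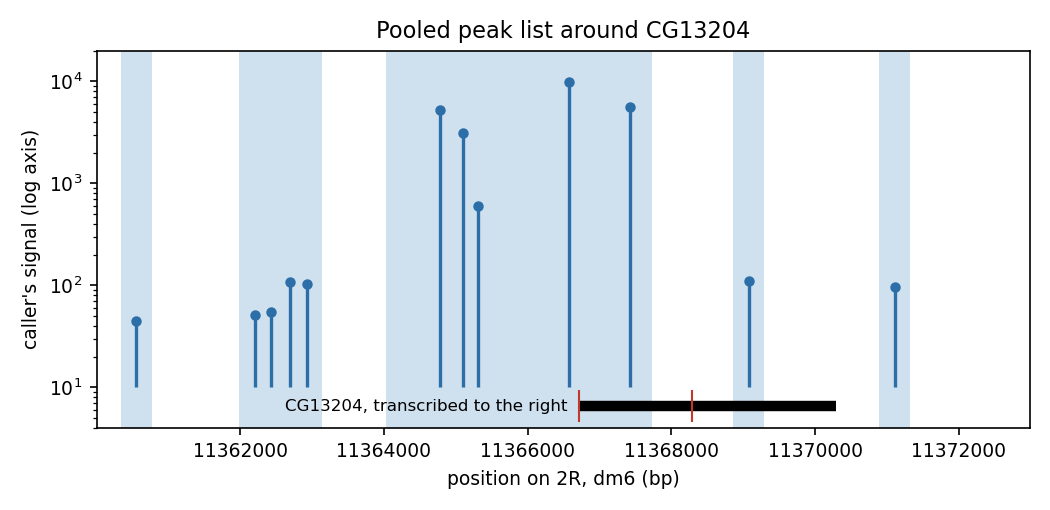
Pooled peak list around CG13204 on 2R: each line is a summit, its height the caller's signal on a log axis, with peak intervals shaded, the gene as a black bar and its start sites as red ticks. The 5 summits of the 3702-bp region reach 9785, and the summit inside the gene downstream of it reaches 110.

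Other peaks among the 20 strongest lay at genes of varied kinds. The peak next in signal (6942, on 2R at 17392549) had CG10939 as the nearest protein-coding gene, 2044 bp away, but lay 334 bp from the start of the transfer RNA gene tRNA:Ala-TGC-2-1. The peak nearest CG1142 (3073, on 3R at 7474766) likewise lay 230 bp from the start of snRNA:7SKa, a small nuclear RNA gene, and that nearest CG31249 (2860.33, on 3R at 17701013) lay inside osa, which encodes a subunit of a Brahma chromatin-remodelling complex, 272 bp from the start of lncRNA:CR46036. Promoter summits stood 134 bp from CG45071 inside Ctps, the CTP synthase gene (3945), and at Cat, which encodes catalase (3498), Pdss2 (3398), psq, which encodes a DNA-binding protein of GA-rich sites (3319), SNF4Agamma, the gamma subunit gene of AMP-activated protein kinase (3253), snu (3247), larp, which encodes an RNA-binding protein (3117), HmgZ (2870.32), CG15771 (2868) and Ugalt, a UDP-galactose transporter gene (2796). The peak nearest dob (3019.68, on X at 15069523) lay in the 3′ untranslated region of Lsd-2, a lipid droplet protein gene. The strongest distal peaks were 3 of the CG13204 region, an intergenic peak on X at 1399367, 6313 bp from the start of Rilpl (5944), and a peak on 2R at 22569990 in an intron of dnr1 (3895), whose nearest protein-coding start site, 7683 bp away, was that of CG11362.

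Peaks were compared between the replicates to learn how far they recur. Of the 5796 reproducible peaks, 96.8% had a summit within 100 bp in the list of replicate 2 and 96.5% in that of replicate 3, and 93.5% (5417 peaks) had one in both, against 2.82% on average and 3.67% at most over 1000 random placements. Of the 5796 strongest peaks of replicate 2, 69.8% were among the 5796 strongest of replicate 3. Across the 5417 peaks the signal correlated with Spearman's rho of 0.659 and Pearson's r of 0.741 on log2 values (permutation p = 1e-05 for each, the smallest that 100000 permutations can give); this is a correlation across peaks, which are not independent. The log2 ratio of the replicates had an SD of 0.61 around its median of -0.22, so the mean of both replicates has a standard error of 0.30 (a factor of 1.23) for a single peak, below the SD of 0.78 between peaks. The set was chosen on signal pooled from both replicates, which bounds the values that enter the correlation. That choice also builds in much of the overlap with the replicates' own lists, so random placement is no null for that overlap. When intervals had to overlap by at least 50% of both, 76.7% of peaks had a partner in both lists.

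**Figure D2:**
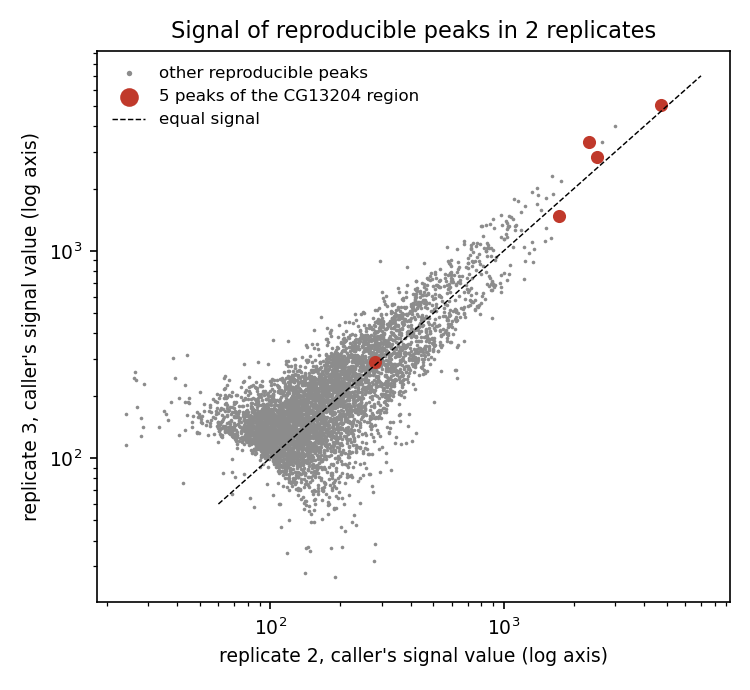
Signal of the 5417 reproducible peaks matched in both replicates, each point a peak, replicate 2 across and replicate 3 upward, both on log axes, with equal signal as a dashed line. The 5 peaks of the CG13204 region (red) include the strongest of both replicates, and rho over all points is 0.659.

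Promoters held more of the peaks than random placement would give, and coding exons held far fewer. Summits within 500 bp of a start site made up 35.2% of the set (2043 peaks) against 15.3% at random, 2.30-fold more. They were set apart first, so their excess lowers the share left for the other locations. Coding exons held 2.78% against 15.4% and 3′ untranslated regions 0.742% against 4.90%, while 5′ untranslated regions held 1.48% against 0.875%. Introns held 42.6% against 39.1% and intergenic sequence 16.1% against 23.5%. Each of these shares differed from random placement with an adjusted p of 0.00233 (n = 5796 peaks, 1000 placements, two-sided, Benjamini-Hochberg over 7 locations; the unadjusted p of 0.002 is the smallest they can give), and non-coding exons did not (1.09% against 0.864%, adjusted p = 0.0939).

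**Figure D3:**
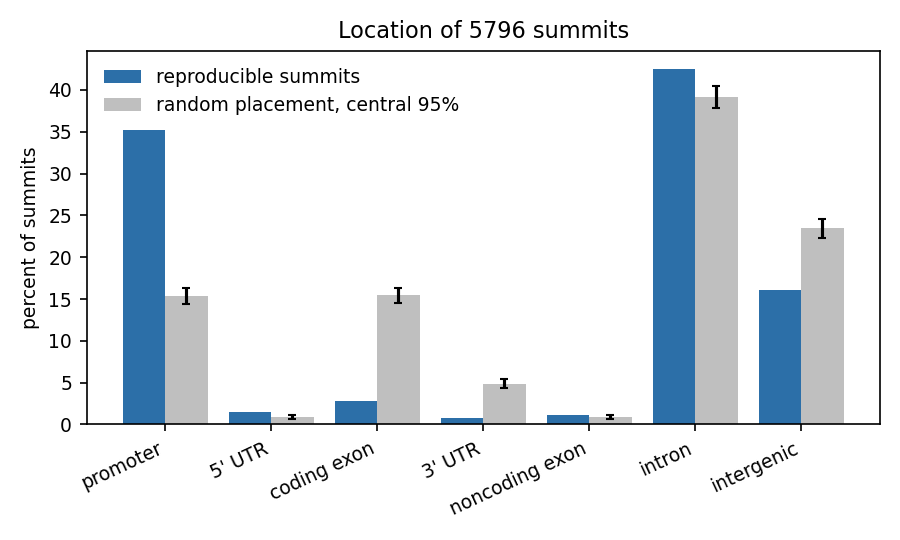
Percent of the 5796 reproducible summits in each kind of annotated sequence (blue) and the mean of 1000 random placements (grey), with bars for the central 95% of placements. Promoter summits stand at 35.2% against 15.3%, and coding exon summits at 2.78% against 15.4%.

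Promoter peaks were slightly stronger than distal ones. The median signal was 349 at the 2043 promoter summits and 307 at the 3753 distal summits, a difference of 0.18 on the log2 scale or 1.13-fold (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The share of promoter summits was 27.8% in the weakest 10% of the peaks and 47.1% in the strongest 10%. The difference was 0.14 without replicate 2, 0.12 without replicate 3 and 0.08 among the stronger 50% of peaks, and the SD of a single peak in 1 replicate was 0.43.

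Genes of the ecdysone response, the programme set off by the steroid hormone that drives metamorphosis, were bound far more often than others. Of 13945 protein-coding genes on the arms, 1530 (11.0%) were bound, and of the 27 genes of this list 19 were (70.4%, exact 95% interval 49.8 to 86.2, odds ratio 19.5, Fisher's exact test, p = 4.9e-13, adjusted p = 1.32e-11). Genes alike in start sites and length, drawn after seeing the data, gave 9.65 bound in place of 19, so part of the excess goes with gene structure. The highest signals stood at Eip93F (1827; on 3R at 21972297, 82 bp from a start site), Eip74EF (1762; on 3L at 17576543, 83 bp), both transcription factor genes, E23, an ABC transporter gene (872), and Eip75B, a nuclear receptor gene (709.55). Also bound, and named after the values were seen, were EcR (432) and usp (271), which encode the subunits of the ecdysone receptor, br (452), Hr3 (401) and ftz-f1 (256), whereas Kr-h1 and Hr39 were not. The Hr3 summit had no match within 100 bp in the list of replicate 3. The list of ecdysteroid synthesis genes had 1 of 11 members bound (mld, 219.98), which did not pass Fisher's exact test (adjusted p = 1).

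Several lists of signalling and developmental genes were bound more often than the background, but of these only the Notch call held against genes alike in start sites and length, a test chosen after seeing the data. In the Notch pathway 13 of 27 genes were bound (odds ratio 7.59, exact test, adjusted p = 1.3e-05), led by the Notch target genes E(spl)mbeta-HLH and E(spl)malpha-BFM, by mib1, a ubiquitin ligase gene, and by numb. In the Hippo growth control pathway 8 of 17 were bound (7.25, exact test, adjusted p = 0.000777), among them dachs, ft, app and kibra, and in the Wnt, Hedgehog and BMP list 13 of 33 (5.31, adjusted p = 0.000148), among them the BMP ligand gene dpp (980), shn, sgg and the Hedgehog receptor gene ptc. Proneural and neural progenitor factors had 8 of 24 bound (4.07, exact test, adjusted p = 0.00815; grh, SoxN, emc and pros), and embryonic patterning transcription factors 13 of 41 (3.79, adjusted p = 0.000983; hry, Poxn, hb and Dll). Axon guidance had 7 of 25 bound (3.17, exact test, adjusted p = 0.0312; robo2, unc-5, robo1 and NetA) and Polycomb and Trithorax proteins 8 of 31 (2.83, adjusted p = 0.0312; ph-p, brm, ph-d and kis), and both calls ended with rotation of the gene order, which keeps neighbouring genes together (adjusted p = 0.0617 and 0.0584). Outside these groups, cytosolic ribosomal proteins had 24 of 93 bound (2.85, exact test, adjusted p = 0.000356), led by RpS4, RpL30, RpS10b and RpL17. Heat shock proteins had 7 of 23 bound (3.56, exact test, adjusted p = 0.0214), led by Hsp27 (1405), Hsp83, DnaJ-1 and Hsc70-5. The heat shock call ended with rotation of the gene order (adjusted p = 0.0617, n = 23 genes), with a start-site window of 250 bp (0.103), among the stronger 50% of peaks (0.154) and without replicate 2 (0.0735). In the last 3 its odds ratio was 3.10, 3.25 and 2.93 against 3.70, all with a small constant added to the counts.

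Of the lists past the threshold, 4 were bound less often than the background. None of 179 chemosensory receptor genes was bound (odds ratio 0, Fisher's exact test, p = 1.58e-09, adjusted p = 2.14e-08; 3 counts of 179, the limit used for a count of 0, allow a share of up to 1.68%, and the exact 95% interval reaches 2.04%) and none of 48 proteasome subunit genes (exact test, adjusted p = 0.0208; up to 6.25% by the same limit, and 7.40% by the exact interval). Cuticle proteins had 2 of 124 bound, Cpr97Ea and Cpr100A (0.132, exact test, adjusted p = 0.000571), and the mitochondrial respiratory chain 1 of 91, ND-ASHI (0.0896, exact test, adjusted p = 0.0017). Without replicate 3 the respiratory chain ratio, from counts with a small constant added, was 0.220 in place of 0.134. With a start-site window of 1000 bp it was 0.320, and that of chemosensory receptors 0.0869 in place of 0.0223, and both calls held. The other 13 lists did not pass; those with the highest shares were the circadian clock (4 of 16; vri and sgg) and Hox genes (2 of 8; Abd-B and abd-A), with muscle structure (6 of 32; Actn and Mef2) and synapse genes (7 of 41; elav and CadN) next. Insulator proteins had 3 of 22 bound (psq and Chro the strongest), cell cycle genes 4 of 36 (Dp and E2f1), translation factors 5 of 50 (eIF4EHP and eIF4H1) and mitochondrial ribosomal proteins 4 of 73 (mRpL41 and mRpL23). A single gene was bound among 14 zinc finger associated domain proteins (hang), 33 immune genes (Dif), 36 germline genes (orb) and 36 spliceosome genes (SmD3). Adjusted p ranged from 0.162 to 1 over these 13 lists (Fisher's exact test). Some genes named as bound had a summit without a match within 100 bp in 1 replicate list. These were brm, Dp and mRpL23 in replicate 3, like Hr3, and robo1 and orb in replicate 2.

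Long genes with many start sites have more windows in which a summit can fall, and the test against genes alike drew genes matched in both. The ecdysone response then had 19 genes bound against 9.65 expected, the Notch pathway 13 against 3.68, ribosomal proteins 24 against 4.41 and chemosensory receptors 0 against 9.73 (adjusted p = 0.0027 for each, n = 27 to 179 genes a list, with genes taken as independent). Against these draws the calls of the patterning, Wnt, Hedgehog and BMP, Hippo, proneural, axon guidance, Polycomb and Trithorax, proteasome, cuticle and respiratory chain lists ended (adjusted p from 0.117 to 1, n = 17 to 124 genes a list). Patterning factors had 13 bound against 7.46 expected, the Wnt, Hedgehog and BMP list 13 against 8.55, the Hippo pathway 8 against 4.32, proneural factors 8 against 4.61, axon guidance 7 against 7.30 and Polycomb and Trithorax proteins 8 against 5.87. Proteasome subunits had 0 against 2.09, cuticle proteins 2 against 5.36 and the respiratory chain 1 against 5.73. Synapse genes were bound less often than genes alike (n = 41 genes, 7 bound against 14.5 expected, adjusted p = 0.0477, but 13.6 expected and 0.0999 matched in classes). The call of heat shock proteins stood at 0.0477 or, matched in classes, 0.0508. Without replicate 3 the axon guidance odds ratio fell from 3.30 to 2.13, both with a small constant added to the counts (Fisher's exact test, adjusted p = 0.305). With a start-site window of 250 bp the calls of the Hippo (odds ratio 3.47 against 7.29) and the Polycomb and Trithorax lists (2.16 against 2.94) ended too. Among the stronger 50% of peaks those of the proteasome (0.144 against 0.0833), proneural (3.09 against 4.20), axon guidance (2.19 against 3.30) and respiratory chain lists (0.231 against 0.134) ended. These ratios too are from counts with a small constant added. Summits found in both replicate lists, chosen after seeing the data, ended those of axon guidance and of Polycomb and Trithorax proteins (Fisher's exact test, adjusted p = 0.0754 for each), with odds ratios of 2.88 against 3.30 and 2.65 against 2.94.

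**Figure D4:**
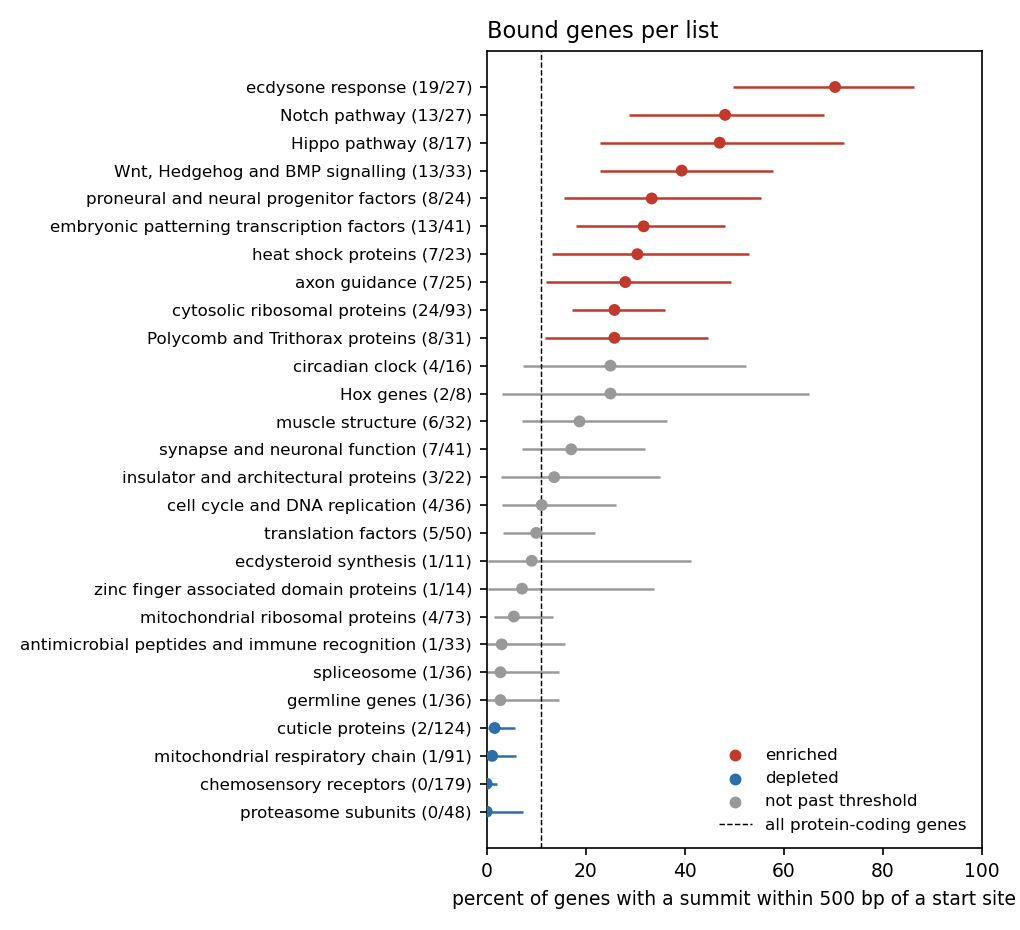
Percent of the genes of each list that were bound, with exact 95% intervals and the number bound of the number tested; red lists were enriched and blue lists depleted in Fisher's exact test, and the dashed line is 11.0% of all protein-coding genes. The ecdysone response list stands at 70.4%, and no chemosensory receptor gene was bound.

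Genes on X were bound more often than autosomal genes in these mixed-sex pupae. On X 308 of 2196 protein-coding genes were bound (14.0%) and on 2L, 2R, 3L and 3R 1222 of 11669 (10.5%), an odds ratio of 1.39 (Fisher's exact test, p = 2.32e-06). On simulated data this test called random gene sets too often, at 13.5%, so its p is too small; draws of as many random start sites, chosen after seeing the data, gave odds ratios from 0.913 to 1.21 (n = 308 bound genes, p = 0.002, the smallest they can give). Against autosomal genes alike in start sites and length the excess was 1.11-fold, 308 against 277 expected (n = 308 bound genes, p = 0.0256, with genes taken as independent). Reproducible peaks were less dense on X (43.0 per Mb) than on 2R (48.8) and 3L (45.9) and denser than on 3R (40.8) and 2L (40.3).

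GA repeats had the highest odds ratios of the 24 motifs at the summits. The GAGA element, the site of the Trithorax-like protein, occurred in 12.1% of the 5796 summit windows and 3.87% of 10980 flanking windows (odds ratio 3.41, 95% interval 3.01 to 3.86, Fisher's exact test, p = 2.24e-85, adjusted p = 5.37e-84). The longer GA repeat bound by CLAMP occurred in 3.31% against 0.883% (3.84, 3.00 to 4.90, exact test, adjusted p = 9.53e-28). It contains the GAGA element, so its windows are part of the GAGA excess and not a separate one. With a small constant added to the counts its odds ratio was 23.4 against shuffled windows and, in controls chosen after seeing the data, 21.5 against GC-matched windows and 8.69 against those outside coding exons. The Grainyhead site was rarer and also more frequent at summits (0.604% against 0.301%, odds ratio 2.02, exact test, adjusted p = 0.00922), and at 2.14 among the stronger 50% of peaks, with fewer windows, it did not pass (adjusted p = 0.0534). Its odds ratio was 3.54 without replicate 2, and 5.41 and 3.69 against the same GC-matched windows. The homeodomain site TAATTA (6.75% against 13.2%, odds ratio 0.477) and the nuclear receptor site AGGTCA (2.74% against 4.96%, 0.540) were less frequent at summits (exact test, adjusted p = 3.32e-38 and 1.19e-11). In all 13 of 24 motifs passed, 6 of them more frequent at summits, but summit windows were richer in G and C (46.7%) than flanks (41.9%). Against windows of like GC content outside coding exons, chosen after seeing the data, the calls of CAGCTG, Motif 7, the CTCF core, the BEAF-32 core, GATA and AP-1 ended and the TATA box turned from 0.823 to 1.17. That control also gave calls that the flanks did not, with Motif 1 at 2.76 and Mef2 at 2.05 more frequent and the Pho core (0.727), Scalloped site (0.830) and CACGTG (0.798) less frequent. Shuffled windows ended the call of TAATTA (Fisher's exact test, adjusted p = 0.628).

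**Figure D5:**
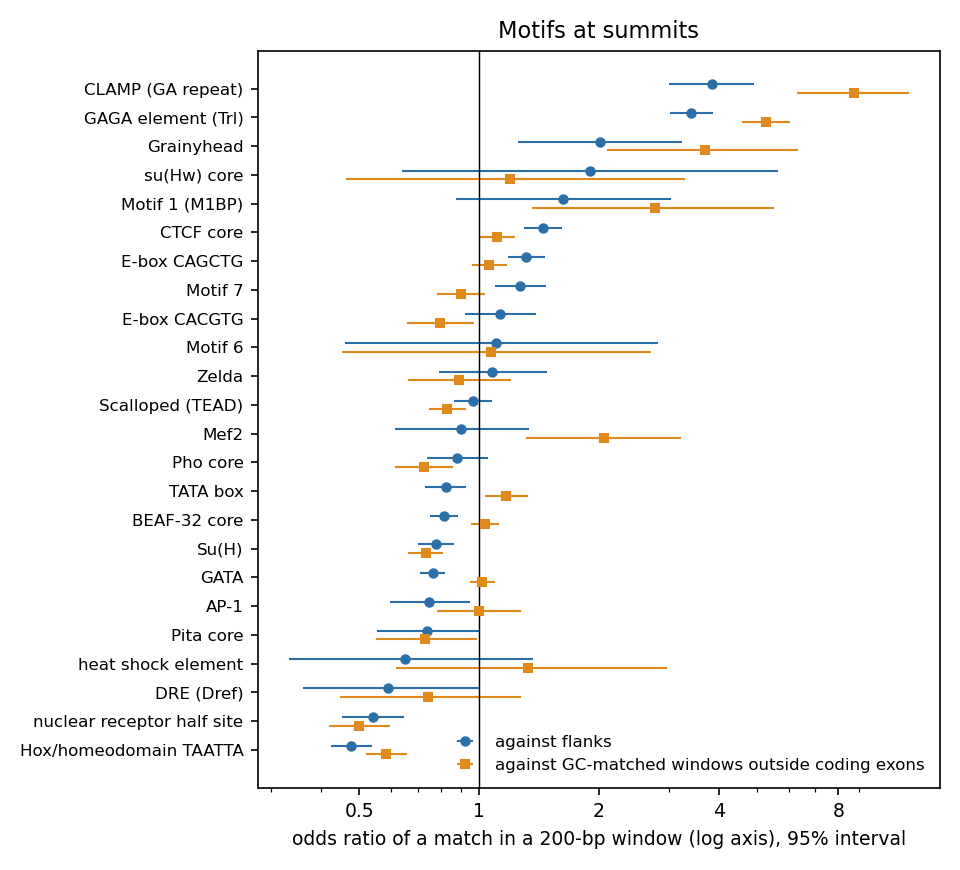
Odds ratio, on a log axis, of a motif match in the 200-bp summit windows against flanking windows (blue circles) and against windows of like GC content outside coding exons (orange squares), with 95% intervals. The GAGA element stands at 3.41 and 5.26, and TAATTA lies below 1 in both.

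Among all 6-mers, those of GA-rich and of GC-rich sequence led. Of 2080 6-mers 587 were more and 806 less frequent at summits than in flanks (Fisher's exact test, Benjamini-Hochberg). The leading ones were CCGCTC (18.8% against 7.18%, odds ratio 3.00), AGAGAG (21.4% against 9.21%, 2.69), AGAGCG (19.3% against 7.81%, 2.83) and GAGCGA (20.4% against 9.03%, 2.59). CAATTA (9.97% against 19.1%, 0.469) and AATTAG (6.47% against 14.3%, 0.416) were the most depleted by p. In a split of the peaks into random groups of equal size, 79.9% of the 1120 6-mers called in the first were called in the same direction in the second. Against GC-matched windows 352 of the 587 and 527 of the 806 were called in the same direction.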

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

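Alternatives that match genes, or windows on GC content, or keep summits of both replicate lists were chosen after seeing the data. The share of peaks found in both replicates, 93.5%, was 97.7% with summits within 200 bp, 98.8% with any overlap of intervals, 76.7% with an overlap of at least 50% of both, and 96.0% among the stronger 50% of peaks. The number of gene lists past the threshold, 14, was 9 among the stronger 50% of peaks, where fewer genes are bound, 11 with rotation of the gene order and 12 with summits found in both replicate lists. It was 4 against genes in the same class of start sites and length. Against the nearest genes in both it was 6, made up of 5 of the 14 and, as a deficit, the synapse list. The cause of each change was not tested. Axon guidance had an odds ratio above 1, and in these matched draws its ratios of genes bound to genes expected were 0.972 and 0.962, with a small constant added. With 7 genes bound against 7.22 and 7.30 expected, the draws showed no clear difference, not a reversal. Against shuffled windows the BEAF-32 core turned to an odds ratio of 1.13, Motif 7 to 0.874, the TATA box to 1.65 and Su(H) to 1.13. Against GC-matched windows CAGCTG turned to 0.996, the TATA box to 1.35, GATA to 1.00 and AP-1 to 1.28, and outside coding exons the BEAF-32 core to 1.03, Motif 7 to 0.901, the TATA box to 1.17 and GATA to 1.02; the cause was not tested. The promoter share, promoter signal, X share, rank correlation and the numbers of motifs and 6-mers kept their direction and their side of the threshold, or stayed within 1.5 times, in all alternatives run. With 1 replicate left out in turn, promoter enrichment ranged from 2.29 to 2.36 and 13 lists passed each time. AP-1 lost its call without replicate 2 (Fisher's exact test, adjusted p = 0.352) and the TATA box without replicate 3 (0.625). Both calls also ended among the stronger 50% of peaks, and that of AP-1 with windows of 50 bp on each side and with distal peaks alone. Keeping all chromosomes changed nothing, since no peak lay elsewhere. Read depth was unknown, so the limit it sets on weak peaks cannot be given.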

Other observations

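The genes below were chosen after their values were seen. The protein-coding genes with the most reproducible summits in the gene or within 500 bp were jing (32), sbb (29), Eip75B (26), EcR, mam and tara (25 each), Snoo (24) and Eip74EF (23), most of them distal to start sites (80.8% at Eip75B, 88% at EcR and 87.0% at Eip74EF). These genes are long, jing 120 kb and Eip75B 114 kb, and kirre, with 394 kb, had 19. Per 10 kb tara, a gene of 34.7 kb, had 7.01 summits and osa 5.07, against 2.27 at Eip75B and 0.481 at kirre. In all 2207 protein-coding genes held a summit, 55 of them 10 or more.

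Chromosome 4 held few peaks: 5, or 3.71 per Mb, against 43.7 per Mb on the other arms, and none of its 80 protein-coding genes was bound against 11.0% elsewhere (Fisher's exact test, p = 0.000193, chosen after seeing the data). The relaxed pooled list held 15 peaks there, 11.1 per Mb against 211 to 236 on the other arms. The deficit was thus present among weak listed peaks too, and its cause was not tested. Among non-coding genes, 14 of 290 transfer RNA genes (4.83%), 4 of 269 small nucleolar RNA genes (1.49%) and 305 of 3261 other non-coding RNA genes (9.35%) were bound. The GAGA element occurred in 16.6% of promoter and 9.62% of distal summit windows, in 10.3% of the strongest 10% of peaks and 11.4% of the weakest 10%, and in 5.47% of the pooled peaks below the threshold.

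Technical explanations were weighed for 3 patterns; the tests of gene structure, of GC content and of an even rise over CG13204 were chosen after the result was seen. No biological explanation was tested, since the samples form 1 group. For the strongest and widest region, at CG13204, extra copies of a large construct around the gene could raise the number of weak peaks nearby. The relaxed pooled list held 6 peaks 2 to 20 kb from the edges of the region, against a median of 6 over protein-coding genes (percentile 56.0). For those genes the distance ran from their start sites, so the counts are not alike. They cannot show whether such a rise was present. Weak peaks within 2 kb of the region were listed but not counted, though those upstream lay over 2 kb from the start sites of CG13204. Copies that were also in the control, or that ended within 2 kb, need not give such a rise. The count therefore does not exclude extra copies. The strongest peak in the rest of the gene reached 1.12% of the region's strongest, but the region's own limits set what the rest is, so this does not exclude an even rise over the gene. The list covered 16.8% of the 2561 bp of the gene downstream of the region, between the values that would decide on a raised signal over the whole gene. Binding of the fusion protein at its own gene and an effect of the inserted construct on the region itself cannot be told apart by these lists.

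For the gene lists, length and number of start sites were weighed as the cause of each excess or deficit. Draws of the nearest genes in both left an adjusted p of 0.0027 for the ecdysone response (9.65 expected, 19 bound), the Notch pathway (3.68 expected, 13 bound), cytosolic ribosomal proteins (4.41 expected, 24 bound) and chemosensory receptors (9.73 expected, 0 bound), which argues against gene structure as the whole cause there. The draws took genes as independent, while several bound Notch genes lie together on 3R. For axon guidance (adjusted p = 1, n = 25 genes), Polycomb and Trithorax proteins (0.682), Wnt, Hedgehog and BMP signalling (0.180), proteasome subunits (0.447) and cuticle proteins (0.353), gene structure is a candidate explanation, since genes alike in it gave at least 50% of the difference from the background. The lists of patterning factors (0.117), the Hippo pathway (0.139), proneural factors (0.183), the respiratory chain (0.117) and heat shock proteins (0.0477, or 0.0508 in classes) stay open, as genes alike gave under 50% of the difference from the background while the adjusted p in at least 1 matching was over 0.05; for heat shock proteins genes alike gave 2.49 bound, near the 2.52 of the background, against 7 found.

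For the GAGA element, base composition and long GA repeats were weighed. The odds ratio was 8.71 (7.35 to 10.3) against windows of like GC content and 5.26 (4.57 to 6.04) against such windows outside coding exons, and 3.21 (2.77 to 3.71) against flanks after 215 summit windows with GA or AG repeated 5 or more times on either strand were left out. These values argue against both as the whole cause. Open chromatin shared by many factors may give the same excess and was not tested, since no other factor's peaks were used here.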
